A study of Mus musculus with 79 samples.

How the data were processed

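RNA from mouse ESCs, EpiLCs and embryoid bodies of 4 lines was measured in 79 libraries. Per the labels' protocols, RNA was isolated with column kits, treated with DNase and made into strand-specific libraries after oligo-dT capture. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.1 and cutadapt 1.18 and aligned with HISAT2 2.1.0 to GRCm38. The counting tool and the annotation release are not given in the sources used here.

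The authors deposited 1 table of log2 RPKM values, with a symbol, an Ensembl identifier and GRCm38 coordinates for each gene and a column for each library. Its unit was read from the deposited table's name and tested on the values, in which low genes fell on steps of whole reads. With a gene without a read taken as 0.9 reads, 98.5% of the deposited log2 values up to 20 reads, in genes with libraries at 0 and 1 read, corresponded to whole reads within a tolerance of 0.1. Gene lengths recovered in this way equalled the merged exons of GENCODE M21 for 97.6% of these genes. Over all genes with a recovered length, 98% of values between 1 and 100 reads were whole, and 13 genes gave no length. The recovered depth was 7.76 to 13.9 M reads per library, with a median of 11.2 M.

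Groups were taken from the labels, as genotype and condition, which gave 28 groups of 2 or 3 libraries. Of the columns, 1 matched only its group (DNMT WT at EpiLC D1) and was used as a replicate without a number. Replicate numbers are shared across groups, but nothing in the labels says that equal numbers mean a common culture or day, so they were not used as a block. Replicates of a group correlated at 0.983 or above (median 0.994, log2 scale, across genes), and over 74 replicate pairs the chi-square per gene between recovered reads of genes with at least 20 reads was 2.15 to 142, so no pair was taken for 1 library deposited in duplicate. Principal components of the 2000 most variable genes held 55.5%, 12.2% and 6.5% of the variance.

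The table held 35269 entries. Where an identifier had more than 1, that with the highest mean was kept, which left out 39 and gave 35230 genes. Genes with at least 1 RPKM in at least 2 of the 79 libraries were tested (15267 genes). Values were converted to log2(RPKM + 0.5), a scale on which the change of low genes is understated, and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend and robust settings). Each knockout comparison was fitted on the libraries of all 4 genotypes at that condition, and each comparison with ESC D0 on all 4 genotypes at both conditions. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 and a log2 change of at least 1 in size. Adjusted p-values of genes are from limma throughout. The comparisons were each knockout with its parental line at the 7 conditions, each condition with ESC D0 within a line, the difference between the DNMT KO and TET KO effects, and the difference of the response to differentiation between knockout and parental line.

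A set of 25 gene lists was tested with camera in limma, at a preset correlation between genes of 0.01 and two-sided, adjusted over 350 tests for the knockout comparisons and within each other kind of comparison. For the difference between the knockout effects and the difference of the response, lists were not tested at EpiLC D1 or EB D2. The lists were the Tet and Dnmt enzymes, other DNA methylation machinery, naive, general, and formative and primed pluripotency, primitive streak and early mesoderm, haematoendothelial, blood lineage, erythroid and globin, cardiac muscle, endoderm, neuroectoderm, mesenchyme and smooth muscle, trophoblast, methylation-sensitive germline genes, the Rhox cluster, imprinted genes, two-cell-like genes, Hox genes, p53 targets, interferon response, Wnt targets, Nodal pathway, housekeeping and mitochondrially encoded genes. Camera with a correlation estimated from the residuals and fry, which tests whether the genes of a set move one way on balance without comparing it with other genes, were alternatives. The counts of called list members were also adjusted over the list alone. The directions of list medians with an adjusted p under 0.05 in the knockout comparisons were checked under both other scalings, and 0 of them turned. Zscan4, Usp17l, Hist1h2a, alpha-globin and Rhox genes have close copies that share sequence, so values of single members are uncertain.

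Named genes followed a rule: the targeted genes in every comparison; the 10 largest rises and 10 largest falls at EB D8 in each knockout and in TET WT against ESC D0, and 5 and 5 at ESC D0 and EpiLC D2, among called genes whose libraries did not overlap between groups, with a mean of at least 5 RPKM in the higher group and no clone or predicted-gene name; up to 4 called members with the largest change of each list described; and Gata1, Runx1, Tal1, Kdr and Hbb-bh1 at EB D8. Genes named as markers of a line, such as Rpl29 across all conditions, Gm42418 and the Y-linked genes, were chosen after their values were seen. The groups, tests, lists, naming rule and all alternatives except 3 were set before the data were examined.

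The tests were checked on simulated data, with 200 of 15267 genes changed. At log2 changes of 1.5 and 3 the fit recovered 100% and 100% of changed genes in the layout of TET KO at EB D8, 99% and 100% for DNMT KO at EB D8, 97% and 100% for DNMT KO at EB D2, and 99% and 98% for DNMT KO at ESC D0. Unchanged genes called numbered 0, 0, 1 and 1 in these layouts, and 0 of 24 unshifted lists were called in each. The noise was drawn independently for each gene, and the changed genes had a mean above 1 on the log2 scale. The simulation therefore tested neither lists of correlated genes nor the recovery of low genes.

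Alternatives covered the pseudocount (0.1 and 1 RPKM, and the deposited log2 values with none), no filter, quantile normalization, centring of each library on its median, the libraries in the fit, the replicate number as a block, and leaving out each replicate in turn. Added after the data were seen were limma's voom on the recovered reads, leaving out libraries with over 2% of reads on Gm42418, and leaving out genes of chromosomes 8 and 14. Chromosome medians used the 10228 tested genes with a mean of at least 2 RPKM. Tables were handled with the data.table package (1.17.8), and with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.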

Results

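Strand-specific RNA sequencing with oligo-dT capture was read from 79 libraries of mouse embryonic stem cells (ESCs) and their derivatives. The 4 genotypes were a line lacking Tet1, Tet2 and Tet3 (TET KO), whose products oxidise methylated cytosine, its parental line (TET WT), a line lacking the DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b (DNMT KO), and its own parental line (DNMT WT). Each was sampled at 7 conditions: ESCs in 2i/LIF at day 0 (ESC D0), days 1 and 2 of conversion to epiblast-like cells (EpiLC D1 and D2), and days 2, 4, 6 and 8 as embryoid bodies (EB D2 to D8). Of the 28 groups, 23 had 3 libraries, and 5 had 2: TET KO at EB D2, DNMT WT at ESC D0, EpiLC D1 and EB D4, and DNMT KO at EB D2. Reads recovered from the deposited values numbered 7.76 to 13.9 M per library (median 11.2 M), and 1 read on a 2 kb gene was worth 0.0644 RPKM in the shallowest library. A gene without a read carries the value of 0.9 reads, a floor that depends on gene length and depth. Levels are mean RPKM ± SD, and the knockout stands first unless stated. Between a knockout and its parental line, a rise or fall means higher or lower in the knockout at that condition. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples only. Each genotype was 1 line, so the effect of a knockout and other differences between the lines cannot be told apart. Of 35230 genes, 15267 were tested, and a gene was called at an adjusted p under 0.05 and a log2 change of at least 1 in size.

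The targeted genes were read first, as a check of the labels. Dnmt1 (ENSMUSG00000004099, GRCm38 chromosome 9:20907209-20959888), which maintains methylation after replication, lay between 3.63 and 6.49 RPKM in all 20 DNMT KO libraries and between 39.4 and 63.2 in the parental libraries. Dnmt3a (ENSMUSG00000020661, chromosome 12:3806007-3914443) spanned 0.339 to 4.94 RPKM in DNMT KO and 1.63 to 60.3 in DNMT WT. For Dnmt3b (ENSMUSG00000027478, chromosome 2:153649450-153687730) the ranges were 3.03 to 58.6 and 24.0 to 382. Dnmt1 and Dnmt3a were called lower at all 7 conditions, and Dnmt3b at all except EB D8, where it missed the size threshold (12.6 ± 0.54 against 24.3 ± 0.428, log2 change -0.92, adjusted p = 6.83e-06). With the replicate number as a block, Dnmt1 and Dnmt3b were not called at EB D2 (adjusted p = 0.129 and 0.161). Ranges of the Tet genes overlapped between TET KO and TET WT. Tet1 (ENSMUSG00000047146, chromosome 10:62804570-62908996) spanned 2.52 to 13.5 RPKM in TET KO and 2.33 to 26.3 in TET WT. It was called lower in the knockout at ESC D0 (8.32 ± 0.94 against 23.6 ± 1.89, log2 change -1.45), EpiLC D1, EB D2 and EB D4. The call was lost at EB D2 with the replicate number as a block (adjusted p = 0.0645) and at EB D4 without TET WT replicate 1 (log2 change -0.96). Tet1 was not called at EpiLC D2 (11.6 ± 2.2 against 12.2 ± 6.11, log2 change 0.01, adjusted p = 0.968), EB D6 or EB D8 (2.98 ± 0.453 against 2.56 ± 0.218, log2 change 0.18, adjusted p = 0.131). Tet2 (ENSMUSG00000040943, chromosome 3:133463679-133545139) spanned 0.810 to 8.09 and 0.771 to 12.6 RPKM, and was called lower at EB D2 only, with log2 changes of 0.42 at EB D6 and 0.41 at EB D8, below the size threshold. Tet3 (ENSMUSG00000034832, chromosome 6:83362373-83459084) spanned 0.121 to 7.39 and 0.268 to 8.95 and was called at no condition, although at EpiLC D1 it was called lower with a pseudocount of 0.1 RPKM (log2 change -1.05), with none (-1.47) and with voom (-1.49). The deleted exons are not given in the sources used here, and reads outside them check nothing, so whole-gene levels tested the TET labels only in part. Rpl29 (ENSMUSG00000048758, chromosome 9:106429454-106431568), a ribosomal protein gene, was a marker of the TET KO line, at 86.7 to 131 RPKM in its 20 libraries and 2.94 to 15.2 in the 59 others.

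The lines also differed by chromosome (medians of chromosomes are given minus the median of all genes). Genes of chromosome 8 were lower in TET KO than in TET WT at every condition (median log2 change -0.44 at ESC D0 over 604 genes, -0.46 at EB D8). On chromosome 14 the median was -0.46 over 352 genes at ESC D0, -0.33 at EB D4 and 0.02 at EB D8. At EB D8 the medians of chromosomes 6 and 11 were -0.34 and -0.23. On these 2 chromosomes TET WT then stood 0.34 and 0.25 above DNMT WT, and TET KO 0.01 and 0.03 above it. The shift there thus lay in the parental line. Between DNMT KO and DNMT WT the chromosome medians stayed within 0.10 of 0. Y-linked Ddx3y, Uty and Eif2s3y were lower in DNMT KO at all 7 conditions, as for Eif2s3y at ESC D0 (3.08 ± 0.348 against 13.5 ± 0.255 RPKM). Leaving out genes of chromosomes 8 and 14 lowered the TET KO counts to 925 of 1035 at ESC D0 and 1387 of 1524 at EB D8. Genes of chromosomes 6 and 11 were not left out.

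**Figure D1:**
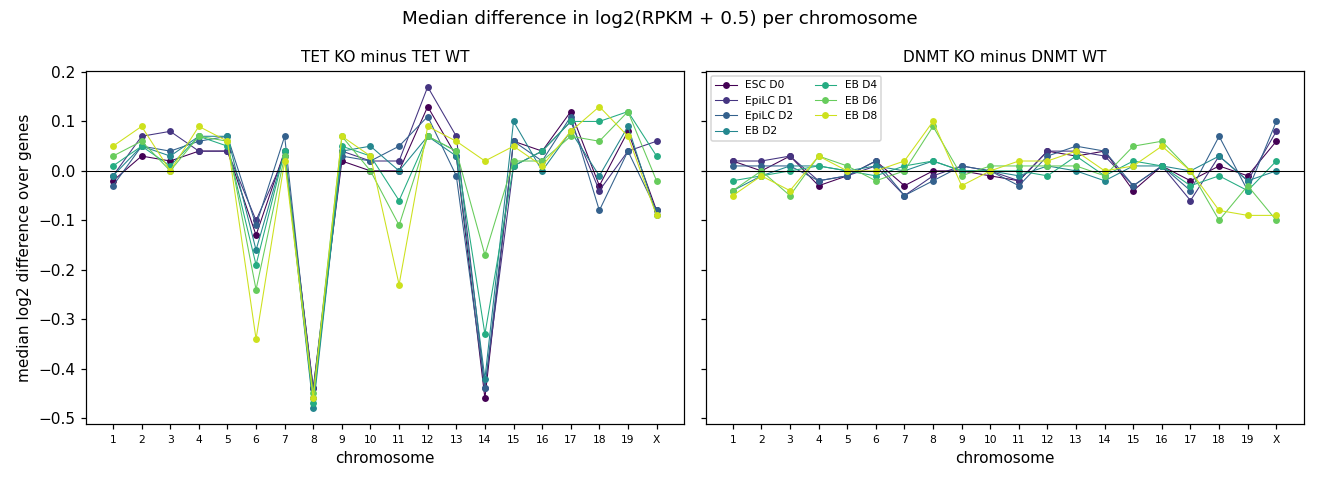
Median log2 change, minus the median of all genes, between TET KO and TET WT, and between DNMT KO and DNMT WT, for each chromosome (horizontal axis) at the 7 conditions. Chromosome 8 lay near -0.45 in TET KO throughout, and chromosome 14 moved from -0.46 at ESC D0 to 0.02 at EB D8.

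Scaling mattered for the direction of calls. Centring each library on its median moved the median change of all genes in TET KO by -0.125 at ESC D0, 0.116 at EpiLC D1, -0.298 at EB D4, -0.109 at EB D6 and -0.159 at EB D8. In the wild-type lines it moved that median by 0.296 in TET WT at EpiLC D2, -0.266 in TET WT at EB D8 and -0.305 in DNMT WT at EB D8. List medians below are therefore given relative to the median of all genes tested in the same comparison. Gene lists were fixed before the data were examined, and list p-values are from camera with its preset correlation, followed by those with an estimated correlation. In the comparisons of a knockout with its parental line, counts adjusted over the list alone equalled those over all genes except in DNMT KO for imprinted genes at EpiLC D1 (5 against 4 higher), two-cell-like genes at EpiLC D1 (9 against 8 lower) and EB D2 (3 against 2 lower), and the Rhox cluster at EB D2 (3 against 1 higher).

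Differentiation of the wild-type lines gave the course against which the knockouts were read. In TET WT, EB D8 against ESC D0 called 4994 genes, 3104 higher and 1890 lower (62.2% higher, 46.7% after centring and 51.4% after quantile normalization). All 16 naive pluripotency genes fell (median -4.37, adjusted p = 8.95e-10, estimated-correlation adjusted p = 0.0309). Among these were the transcription factors Nanog, at 8.37 ± 0.629 against 467 ± 6.8 RPKM, and Esrrb, at 1.95 ± 0.216 against 124 ± 1.68 (n = 3 and 3). General pluripotency genes fell in 8 of 10 cases with 1 higher (median -3.28, adjusted p = 6.14e-05, estimated-correlation adjusted p = 0.131). Pou5f1 stood at 13.1 ± 1.71 against 460 ± 2.76. Erythroid and globin genes rose in 16 of 17 cases (median 5.9, adjusted p = 2.77e-08, estimated-correlation adjusted p = 0.0171). The embryonic globin Hbb-bh1 (ENSMUSG00000052217, chromosome 7) had no read in any ESC D0 library and reached 5074 ± 253 RPKM. Blood lineage genes rose in 12 of 16 cases (median 3.36, adjusted p = 0.00015, estimated-correlation adjusted p = 0.025) and haematoendothelial genes in 19 of 21, with 1 lower (median 3.13, adjusted p = 4.79e-06, estimated-correlation adjusted p = 0.0462). Endoderm genes rose in 17 of 17 cases (median 4.7, adjusted p = 3.32e-09, estimated-correlation adjusted p = 0.00254), led by the retinol carrier Rbp4 at 354 ± 43 RPKM, and cardiac muscle genes in 16 of 17 (median 2.96, adjusted p = 3.48e-06, estimated-correlation adjusted p = 0.0595). Imprinted genes rose in 21 of 25 cases (median 2.9, adjusted p = 3.22e-10, estimated-correlation adjusted p = 0.00101). The imprinted RNA H19 stood at 1697 ± 117 RPKM and no read in any ESC D0 library. Mesenchyme and smooth muscle genes rose in 12 of 14 cases (median 3.95, adjusted p = 2.84e-05, estimated-correlation adjusted p = 0.0373).

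DNMT WT followed a similar course, with 5750 genes called at EB D8 (3552 higher and 2198 lower; 61.8% higher, 46.3% after centring). The parental lines shared 4053 of these calls in the same direction and 14 in opposite directions, and changes correlated across genes with Pearson r = 0.895, although genes are not independent replicates. At EpiLC D2 the lines were further apart: 4219 genes were called in TET WT (42.9% higher, 66% after centring) and 2536 in DNMT WT, 1378 of them shared in direction (r = 0.59 across genes). In TET WT, 12 of 16 naive genes fell at EpiLC D2 (median -2.31, adjusted p = 1.82e-07, estimated-correlation adjusted p = 0.028). Klf4 stood at 3.35 ± 1.78 against 153 ± 0.488 RPKM, and 10 of 13 formative and primed genes rose (median 1.85, adjusted p = 3.52e-05, estimated-correlation adjusted p = 0.0178). Pou3f1 stood at 9.29 ± 1.82 against 0.266 ± 0.0744. Mitochondrially encoded genes were lower in 8 of 9 cases in TET WT at EpiLC D2 (median -1.34, adjusted p = 0.0198, estimated-correlation adjusted p = 0.436), and took 0.14% to 0.16% of reads there, against 0.35% to 0.59% in TET KO at the same condition.

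**Figure D2:**
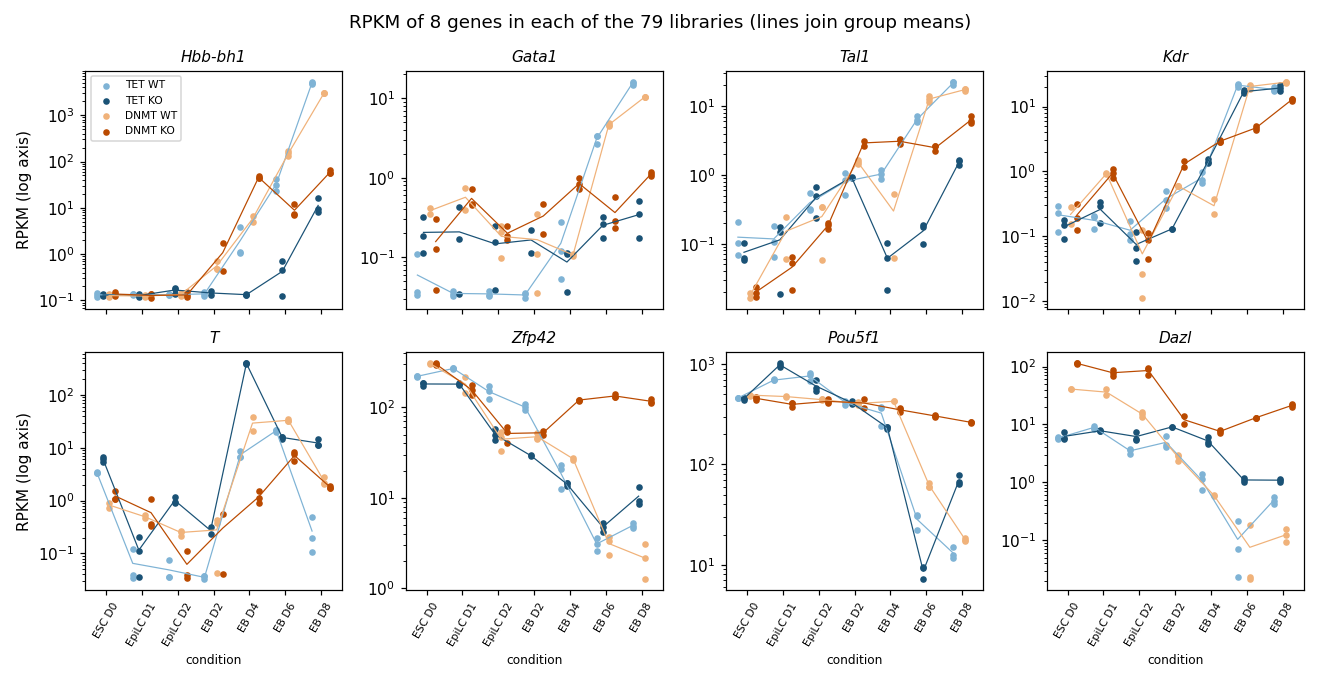
RPKM (log axis) of Hbb-bh1, Gata1, Tal1, Kdr, T, Zfp42, Pou5f1 and Dazl over the 7 conditions in the 4 genotypes, with every library as a point and lines through group means. Genes without a read stand at a floor set by gene length and depth, and Hbb-bh1 ended at 5074 RPKM in TET WT and 11.3 in TET KO at EB D8.

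The comparison of TET KO with TET WT in ESCs and EpiLCs asked what loss of TET activity changed before and at the exit from naive pluripotency. Over all genes tested, the root-mean-square (RMS) log2 distance of TET KO to TET WT was 0.549 at ESC D0, 0.57 at EpiLC D1 and 0.593 at EpiLC D2. Between the parental lines it was 0.623, 0.689 and 0.856. Differences of this size thus also lay between lines without a knockout. At ESC D0, 1035 genes were called, 704 higher and 331 lower (68% higher, 54.9% after centring). Methylation-sensitive germline genes, which are silenced by promoter methylation in somatic cells, were higher in 11 of 22 cases and lower in 1 (median 1.03, adjusted p = 0.00309, estimated-correlation adjusted p = 0.131). Among them were the RNA helicases Mov10l1 (4.46 ± 0.639 against 0.395 ± 0.116 RPKM, n = 3 and 3) and Ddx4 (11.3 ± 0.954 against 2.43 ± 0.298). Among the large rises outside the lists were those of Rpl29 (124 ± 6.19 against 4.89 ± 0.975), AA467197 (16.9 ± 0.824 against 0.127 ± 0.104), Fxyd6 (24.7 ± 1.51 against 1.33 ± 0.242), Tesc (8.97 ± 0.31 against 0.462 ± 0.367) and the germ-cell transcription factor gene Tcfl5 (6.69 ± 0.164 against 0.468 ± 0.192). The oligodendrocyte transcription factor genes Olig2 and Olig1, at 30.1 ± 0.92 and 9.91 ± 0.424 RPKM in TET WT, were under 0.1 RPKM in TET KO, as was the nuclear receptor gene Nr1h5 (15.9 ± 0.934 in TET WT). The apolipoprotein gene Apoc2 (0.107 ± 0.0101 against 12 ± 1.29) and the histone gene Hist1h2ak (1.11 ± 0.998 against 24.6 ± 3.04) were lower. Of the pluripotency lists, 0 of 16 naive and 1 of 10 general genes were called. Hox genes were lower in 4 of 32 cases (median -0.11, adjusted p = 0.0334, estimated-correlation adjusted p = 0.125), and none of the 9 mitochondrially encoded genes was called although their median was lower (median -0.44, adjusted p = 0.00517, estimated-correlation adjusted p = 0.325).

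At EpiLC D1, 1011 genes were called in TET KO (511 higher and 500 lower; 50.5% higher, 64.8% after centring), and 7 of 16 naive genes were lower with 1 higher (median -0.93, adjusted p = 3.17e-05, estimated-correlation adjusted p = 0.134). At EpiLC D2, 1206 genes were called (733 higher and 473 lower; 60.8% higher, 48% after centring), and naive genes were lower in 8 of 16 cases with 1 higher (median -1.08, adjusted p = 0.000226, estimated-correlation adjusted p = 0.16). Among these were Fbxo15 (9.49 ± 0.727 against 48 ± 4.65 RPKM) and Zfp42, which lies on chromosome 8 (50 ± 6.85 against 149 ± 24.3). Of 22 germline genes, 12 were higher and 2 lower (median 1.08, adjusted p = 6.6e-05, estimated-correlation adjusted p = 0.0411), and the piRNA pathway gene Mael stood at 97.2 ± 8.96 against 13.3 ± 1.24. Two-cell-like genes, which mark a rare state with features of the early embryo, were lower in 8 of 14 cases (median -1.1, adjusted p = 7.72e-07, estimated-correlation adjusted p = 0.102). Zscan4d stood at 1.46 ± 0.21 against 7.1 ± 1.25. Of the Nodal pathway, the antagonists Lefty2 (9.95 ± 0.373 against 73.3 ± 6.75) and Lefty1 (74.4 ± 2.01 against 235 ± 13.4) and Gdf3 were lower and 7 of 10 genes were not called (median -0.24, adjusted p = 0.00568, estimated-correlation adjusted p = 0.0921). Formative and primed genes were lower in 3 of 13 cases (median -0.45, adjusted p = 0.0219, estimated-correlation adjusted p = 0.16). Fgf5 stood at 0.924 ± 0.171 against 4.76 ± 0.76. Trophoblast genes were higher in 4 of 10 with 1 lower (median 0.64, adjusted p = 0.0316, estimated-correlation adjusted p = 0.131). Among the large changes outside the lists were those of Plac8 (21 ± 3.35 against 1.9 ± 1.11), Crisp1 (8.97 ± 0.401 against 0.599 ± 0.331) and the histone genes Hist1h2ap (0.805 ± 0.599 against 30.4 ± 5.25) and Hist1h2ao (0.89 ± 0.386 against 21.5 ± 3.01), whose near-identical copies make single values uncertain. Mitochondrially encoded genes were higher in 7 of 9 cases (median 1.51, adjusted p = 0.000244, estimated-correlation adjusted p = 0.325), beside the low mitochondrial share of TET WT at this condition.

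In embryoid bodies the question was how loss of TET activity altered germ layer and blood differentiation. At EB D2, 1131 genes were called in TET KO (718 higher and 413 lower; 63.5% higher, 51.1% after centring; n = 2 and 3), and 10 of 16 naive genes were lower with 1 higher (median -1.28, adjusted p = 1.01e-10, estimated-correlation adjusted p = 0.122). EB D4 gave 1446 calls, 1160 higher and 286 lower (80.2% higher, 51.6% after centring and 57.1% after quantile normalization). In TET WT replicate 2 at EB D4, 15.1% of reads fell on Gm42418, a locus that overlaps ribosomal RNA sequence, and without that library 939 genes were higher and 415 lower. Primitive streak and early mesoderm genes were higher in 13 of 15 cases at EB D4 (median 2.24, adjusted p = 2.73e-11, estimated-correlation adjusted p = 0.0921). The mesoderm regulators T (394 ± 12.9 against 7.4 ± 1.21 RPKM, n = 3 and 3) and Mixl1 (186 ± 1.26 against 1.33 ± 0.532), and the organiser genes Gsc (71.9 ± 5.19 against 2.21 ± 0.435) and Lhx1 (74.6 ± 0.355 against 1.02 ± 0.352), were among them. Interferon response genes were higher in 9 of 13 cases (median 1.72, adjusted p = 3e-07, estimated-correlation adjusted p = 0.0411). Isg15 stood at 15.1 ± 2.43 against 1.28 ± 1.21 and Oasl2 at 9.58 ± 0.549 against 1.02 ± 0.312. Wnt target genes were higher in 5 of 11 cases (median 0.43, adjusted p = 0.0486, estimated-correlation adjusted p = 0.467). Among these were Sp5 (109 ± 2.89 against 3.95 ± 0.794) and Axin2 (29.3 ± 1.4 against 6.62 ± 1.39). Endoderm genes were lower in 10 of 17 cases and higher in 3 (median -1.63, adjusted p = 5.1e-06, estimated-correlation adjusted p = 0.161). The transcription factor genes Gata6 (11.5 ± 1.42 against 0.523 ± 0.0694) and Sox17 (6.94 ± 0.57 against 0.768 ± 0.195) rose. Cubn, a receptor of visceral endoderm, stood at 5.22 ± 0.644 RPKM in TET WT and under 0.1 RPKM in TET KO. Of 10 neuroectoderm genes, 3 were lower (median -0.39, adjusted p = 0.00646, estimated-correlation adjusted p = 0.328). Tubb3 stood at 0.87 ± 0.329 against 13.1 ± 3.2.

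By EB D6, TET KO had 766 called genes (494 higher and 272 lower; 64.5% higher, 50.8% after centring). Streak genes were called in 1 case higher and 1 lower of 15 (median -0.42, adjusted p = 0.0396, estimated-correlation adjusted p = 0.351), and the cardiac mesoderm regulator Mesp1 was lower (4.77 ± 0.303 against 24.1 ± 3.6 RPKM, n = 3 and 3). Haematoendothelial genes were lower in 6 of 21 cases (median -0.66, adjusted p = 4.64e-05, estimated-correlation adjusted p = 0.0734) and blood lineage genes in 7 of 16 (median -0.93, adjusted p = 2.81e-05, estimated-correlation adjusted p = 0.0921). Tal1, a regulator of blood specification, stood at 0.154 ± 0.0491 against 6.46 ± 0.705, Gata1, a regulator of red cell genes, at 0.252 ± 0.0709 against 3.12 ± 0.386, and Hbb-bh1 at 0.424 ± 0.287 against 32.4 ± 9.68, while 4 of 17 erythroid genes were lower (median -0.23, adjusted p = 0.00434, estimated-correlation adjusted p = 0.131). Endoderm genes were lower in 10 of 17 cases (median -1.2, adjusted p = 1.12e-06, estimated-correlation adjusted p = 0.0411). Hox genes, which set position along the body axis, were higher in 16 of 32 cases (median 0.94, adjusted p = 3.73e-07, estimated-correlation adjusted p = 0.0121). Among these were Hoxb9 (5.03 ± 0.429 against 0.104 ± 0.0714) and Hoxc8 (3.22 ± 0.326 against 0.181 ± 0.0748). Germline genes were higher in 15 of 22 cases (median 1.39, adjusted p = 5.26e-08, estimated-correlation adjusted p = 0.0121). Ddx4 stood at 8.02 ± 0.802 against 0.19 ± 0.0915 and Tex19.1 at 9.81 ± 0.213 against 0.371 ± 0.114. Two-cell-like genes were higher in 8 of 14 (median 1.04, adjusted p = 6.33e-05, estimated-correlation adjusted p = 0.116).

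At EB D8, 1524 genes were called in TET KO, 892 higher and 632 lower (58.5% higher, 44.2% after centring). Of the red cell genes, 16 of 17 erythroid and globin genes were lower (median -5.51, adjusted p = 3.01e-17, estimated-correlation adjusted p = 0.0215). Hbb-bh1 stood at 11.3 ± 4.5 against 5074 ± 253, log2 change -8.81 (n = 3 and 3), the alpha-like embryonic globin Hba-x at 5.77 ± 1.93 against 2735 ± 87.6 RPKM and adult Hba-a1 at 1.21 ± 0.478 against 384 ± 23.3. The haem synthesis gene Alas2 (50.7 ± 5.77 in TET WT) was under 0.1 RPKM in TET KO, and the anion exchanger gene Slc4a1 was at 0.109 ± 0.0814 against 52.4 ± 4.5. Blood lineage genes were lower in 13 of 16 cases (median -2.63, adjusted p = 1.18e-12, estimated-correlation adjusted p = 0.0121). Gata1 (ENSMUSG00000031162, chromosome X) stood at 0.343 ± 0.166 against 15.5 ± 0.772, log2 change -4.27, and Nfe2 at 0.103 ± 0.0677 against 12.1 ± 0.784. Upstream, haematoendothelial genes were lower in 7 of 21 cases (median -0.74, adjusted p = 2.55e-05, estimated-correlation adjusted p = 0.14). Tal1 (ENSMUSG00000028717, chromosome 4) stood at 1.55 ± 0.144 against 21.7 ± 1.32, log2 change -3.44, Runx1 (ENSMUSG00000022952, chromosome 16) at 0.882 ± 0.11 against 2.43 ± 0.0991, log2 change -1.09 (-0.87 and not called with a pseudocount of 1 RPKM), and the VEGF receptor gene Kdr (ENSMUSG00000062960, chromosome 5) was not called (19.2 ± 2.1 against 18.3 ± 1.34, log2 change 0.07, adjusted p = 0.482). Endoderm genes were lower in 12 of 17 cases (median -3.37, adjusted p = 1.34e-10, estimated-correlation adjusted p = 0.0121). Among these were Rbp4 (4.96 ± 0.938 against 354 ± 43), the thyroid hormone carrier Ttr (8.6 ± 0.723 against 317 ± 9.19) and Apoa1 (1.3 ± 0.723 against 95 ± 9.89).

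In TET KO at EB D8, formative and primed genes were higher in 10 of 13 cases (median 1.78, adjusted p = 4.82e-05, estimated-correlation adjusted p = 0.122). Fgf5 stood at 24.9 ± 2.44 against 1.04 ± 0.381 RPKM, Zic2 at 23.1 ± 2.78 against 2.32 ± 0.306 and Otx2 at 17.2 ± 2.49 against 2.39 ± 0.629. General pluripotency genes were higher in 7 of 10 cases (median 1.41, adjusted p = 0.000878, estimated-correlation adjusted p = 0.297). Pou5f1 stood at 70 ± 8.23 against 13.1 ± 1.71 and Tdgf1 at 61.8 ± 2.16 against 4.98 ± 0.402. Naive genes were higher in 3 of 16 cases with 3 lower (median 0.56, adjusted p = 0.546, estimated-correlation adjusted p = 0.881). Streak genes were higher in 7 of 15 cases (median 0.49, adjusted p = 0.00952, estimated-correlation adjusted p = 0.341). Among these were T (12.3 ± 1.9 against 0.265 ± 0.202), Fgf8 (17.4 ± 3.02 against 0.988 ± 0.294), Eomes (18 ± 1.01 against 1.74 ± 0.846) and Gsc (7.72 ± 0.312 against 0.357 ± 0.080). Germline genes were higher in 6 of 22 cases (median 0.61, adjusted p = 0.0103, estimated-correlation adjusted p = 0.109) and Rhox genes, an X-linked homeobox cluster, in 4 of 7 (median 1.2, adjusted p = 0.0322, estimated-correlation adjusted p = 0.241). Imprinted genes split, with 4 higher and 6 lower of 25 (median -0.54, adjusted p = 0.00426, estimated-correlation adjusted p = 0.0734), and so did mesenchyme genes, with 3 higher and 4 lower of 14 (median -0.50, adjusted p = 0.0126, estimated-correlation adjusted p = 0.34). Twist1 (87.2 ± 3.37 against 18.8 ± 2.6) rose and Col1a1 (7.14 ± 0.679 against 99 ± 9.6) fell. Cardiac muscle genes were higher in 7 of 17 cases and lower in 1 (median 0.01, adjusted p = 0.892, estimated-correlation adjusted p = 0.966). Myl7 (110 ± 17.1 against 21.1 ± 3.07) and Tnnt2 (18.4 ± 3.37 against 2.85 ± 0.261), parts of the contractile apparatus, rose, and the transcription factor gene Hand1 (15.8 ± 1.73 against 299 ± 19.7) fell. Further single genes were Shisa3 (10.2 ± 2.5 in TET KO, under 0.1 in TET WT), the kinase gene Pim2 (32 ± 3.46 against 2.54 ± 0.292), placental Tpbpa (5.46 ± 1.06 in TET KO, under 0.1 in TET WT), the gut hormone gene Pyy (0.757 ± 0.422 against 83.3 ± 4.15) and Apoc2 (0.17 ± 0.127 against 40.1 ± 1.96).

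The remaining lists did not pass the list test in TET KO at EB D8, with Wnt targets at the threshold. Hox genes were 8 higher and 2 lower of 32 (adjusted p = 0.324), Nodal pathway genes 4 higher and 1 lower of 10 (adjusted p = 0.361), trophoblast genes 5 higher and 2 lower of 10 (adjusted p = 0.829) and neuroectoderm genes 2 higher of 10 (adjusted p = 0.0745). Wnt target genes were higher in 2 of 11 cases (adjusted p = 0.05), interferon response genes in 1 of 13 (adjusted p = 0.801), p53 target genes in 1 of 15 (adjusted p = 0.637), other DNA methylation machinery in 2 of 13 (adjusted p = 0.873) and housekeeping genes in 1 of 10 (adjusted p = 0.546). Of 14 two-cell-like genes and 9 mitochondrially encoded genes, 0 were called (adjusted p = 0.841 and 0.74), and of the 6 Tet and Dnmt genes 1 was higher (adjusted p = 0.252).

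**Figure D3:**
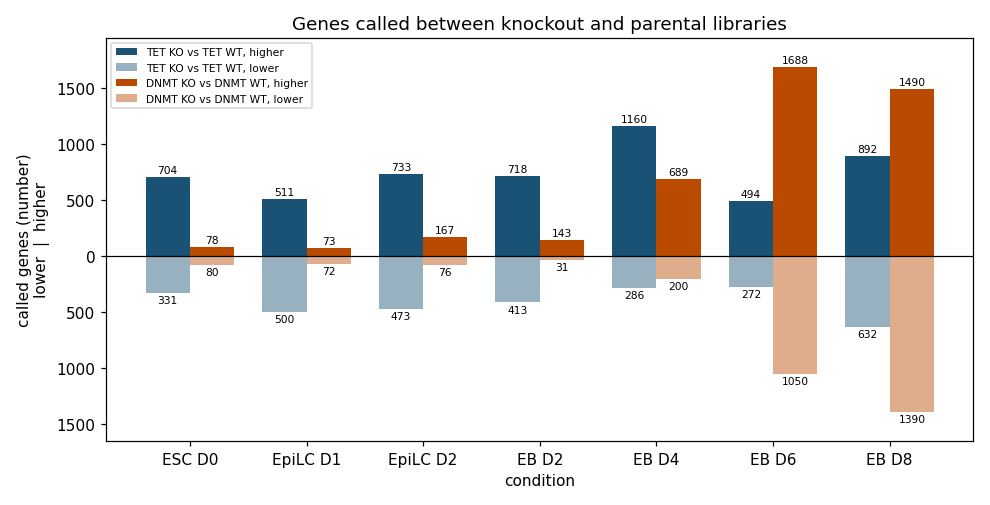
Number of genes called higher (up) and lower (down) in each knockout against its parental line at the 7 conditions. TET KO calls ranged from 766 to 1524, and DNMT KO calls rose from 145 at EpiLC D1 to 2880 at EB D8.

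The comparison of DNMT KO with DNMT WT asked what absence of DNA methylation changed over the same course. Few genes were called before EB D4: 158 at ESC D0 (78 higher and 80 lower; n = 3 and 2), 145 at EpiLC D1 (50.3% higher, 40.1% after centring), 243 at EpiLC D2 (167 higher and 76 lower) and 174 at EB D2 (143 higher and 31 lower; n = 2 and 3). The count at EB D2 was unstable, with 3 genes called with the replicate number as a block. Without DNMT KO replicate 3 only 1 knockout library is left there, so that count is not given. Germline genes were higher in 5 of 22 cases at ESC D0 (median 0.41, adjusted p = 3.73e-07, estimated-correlation adjusted p = 0.0411) and in 8 of 22 at EpiLC D2 (median 0.58, adjusted p = 1.08e-09, estimated-correlation adjusted p = 0.0121), with 0 lower. The germ cell RNA-binding protein gene Dazl stood at 114 ± 2.29 against 40.9 ± 0.329 RPKM at ESC D0 and 85.3 ± 11.7 against 15.1 ± 1.44 at EpiLC D2, and Asz1 at 9.65 ± 1.22 against 1.04 ± 0.385 and 7.77 ± 0.808 against 0.54 ± 0.0563. Among the largest rises at ESC D0 were Magea8 (7.24 ± 1.02 against 0.721 ± 0.131), Magea5 (6.74 ± 1.08 against 1.1 ± 0.137), Scml2 (9.63 ± 0.369 against 1.62 ± 0.112) and Efhc2 (21.9 ± 0.796 against 2.47 ± 0.0461). The methyltransferase cofactor gene Dnmt3l (4.69 ± 0.531 against 26.3 ± 0.683) and Foxd1 (1.03 ± 0.193 against 5.52 ± 0.124) were lower. Two-cell-like genes were lower in 1 of 14 cases at ESC D0 (median -0.52, adjusted p = 3.17e-05, estimated-correlation adjusted p = 0.0411), in 8 at EpiLC D1 (median -1.59, adjusted p = 3.01e-17, estimated-correlation adjusted p = 0.0316) and in 8 at EpiLC D2 (median -1.16, adjusted p = 2.5e-11, estimated-correlation adjusted p = 0.0411). Zscan4d stood at 0.778 ± 0.20 against 5.99 ± 0.54. Imprinted genes were higher in 4 of 25 cases with 1 lower at EpiLC D2 (median 0.20, adjusted p = 0.01, estimated-correlation adjusted p = 0.297). The maternally expressed RNAs Meg3 (7.15 ± 0.632 against 2.59 ± 0.328) and Rian (18.2 ± 0.377 against 6.01 ± 0.126) rose and Phlda2 (12 ± 1.98 against 35.2 ± 2.99) fell. Cd24a, a surface glycoprotein gene, was higher at EpiLC D2 (25.5 ± 4.45 against 4.49 ± 0.202). At EB D2, haematoendothelial genes were higher in 4 of 21 cases (median 0.32, adjusted p = 6.99e-05, estimated-correlation adjusted p = 0.042).

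At EB D4 the DNMT KO bodies diverged, with 889 genes called (689 higher and 200 lower, n = 3 and 2; 77.5% higher, 67.4% after quantile normalization). Naive genes were higher in 13 of 16 cases (median 1.39, adjusted p = 5.17e-12, estimated-correlation adjusted p = 0.153). Zfp42 stood at 120 ± 1.41 against 27.1 ± 1.15 RPKM, and streak genes were lower in 8 of 15 (median -1.41, adjusted p = 8.64e-11, estimated-correlation adjusted p = 0.1). T stood at 1.17 ± 0.299 against 29.3 ± 11.8 and Eomes at 3.36 ± 0.275 against 61.9 ± 9.76. At the same day haematoendothelial genes were higher in 15 of 21 cases (median 1.43, adjusted p = 1.18e-12, estimated-correlation adjusted p = 0.0574). Among these were the endothelial genes Cdh5 (6.56 ± 0.628 against 0.208 ± 0.0399) and Sox18 (10.4 ± 0.896 against 0.479 ± 0.127), and Tal1 (3.09 ± 0.256 against 0.299 ± 0.335). Erythroid genes were higher in 8 of 17 cases (median 0.79, adjusted p = 5.26e-08, estimated-correlation adjusted p = 0.0488). Hbb-bh1 stood at 45.6 ± 2.12 against 5.77 ± 1.2. Endoderm genes were higher in 10 of 17 cases with 1 lower (median 1.11, adjusted p = 2.71e-08, estimated-correlation adjusted p = 0.122). Afp (5.29 ± 0.335 against 0.419 ± 0.252) rose and Foxa2 (0.859 ± 0.35 against 20.6 ± 5.98) fell. Germline genes were higher in 13 of 22 cases with 1 lower (median 1.61, adjusted p = 2.5e-11, estimated-correlation adjusted p = 0.0774), two-cell-like genes in 11 of 14 (median 1.27, adjusted p = 8.5e-08, estimated-correlation adjusted p = 0.0921) and Rhox genes in 6 of 7 (median 1.54, adjusted p = 7.34e-05, estimated-correlation adjusted p = 0.0432).

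At EB D6, 2738 genes were called in DNMT KO (1688 higher and 1050 lower). Naive genes were higher in 14 of 16 cases with 1 lower (median 3.5, adjusted p = 4.41e-07, estimated-correlation adjusted p = 0.0411). Zfp42 stood at 134 ± 4.58 against 3.13 ± 0.713 RPKM and Nr0b1 at 46.1 ± 3.26 against 0.358 ± 0.199. Germline genes were higher in 18 of 22 cases (median 2.81, adjusted p = 1.49e-07, estimated-correlation adjusted p = 0.0121). Among these were the germ cell transcription factor gene Sohlh2 (15.7 ± 0.104 against 0.103 ± 0.0654). Hox genes were lower in 17 of 32 cases with 1 higher (median -1.39, adjusted p = 9.64e-07, estimated-correlation adjusted p = 0.0121). Hoxd9 stood at 0.521 ± 0.121 against 18.1 ± 0.997. Streak genes were lower in 11 of 15 (median -1.58, adjusted p = 1.56e-05, estimated-correlation adjusted p = 0.102). Mesp1 stood at 2.32 ± 1.1 against 41.6 ± 3.85. Cardiac genes were lower in 10 of 17 cases (median -1.54, adjusted p = 0.000104, estimated-correlation adjusted p = 0.0411). Hand1 stood at 3.55 ± 0.166 against 358 ± 14.8. Haematoendothelial genes were lower in 10 of 21 cases with 3 higher (median -0.88, adjusted p = 0.0126, estimated-correlation adjusted p = 0.176). Of 15 p53 target genes, 3 were higher (median 0.53, adjusted p = 0.00088, estimated-correlation adjusted p = 0.115). The cell cycle inhibitor gene Cdkn1a stood at 32.7 ± 1.66 against 12.6 ± 0.886, and of 13 interferon genes 4 were higher (median 0.54, adjusted p = 0.0307, estimated-correlation adjusted p = 0.13).

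DNMT KO at EB D8 had 2880 called genes, 1490 higher and 1390 lower. Germline genes were higher in 18 of 22 cases (median 2.66, adjusted p = 4.35e-08, estimated-correlation adjusted p = 0.0121). Dazl (ENSMUSG00000010592, chromosome 17) stood at 21.3 ± 0.95 against 0.124 ± 0.0297 RPKM and Tex19.1 at 26.5 ± 0.715 against 0.575 ± 0.292 (n = 3 and 3). Sohlh2 stood at 34.8 ± 0.167 in DNMT KO and under 0.1 in DNMT WT. In DNMT KO at ESC D0, Sohlh2, Dazl and Tex19.1 stood at 34.2, 114 and 104 RPKM. The level in DNMT KO at EB D8 was thus about the same for Sohlh2 and lower for Dazl and Tex19.1. Naive genes were higher in 13 of 16 cases (median 4.08, adjusted p = 1.5e-07, estimated-correlation adjusted p = 0.125). Zfp42 (ENSMUSG00000051176, chromosome 8) stood at 117 ± 7.11 against 2.17 ± 0.924 and Esrrb at 50.7 ± 0.844 against 0.789 ± 0.0644. General pluripotency genes were higher in 8 of 10 (median 4.29, adjusted p = 5.78e-06, estimated-correlation adjusted p = 0.16). Dppa2 stood at 33.8 ± 2.19 against 0.252 ± 0.0663 and Utf1 at 132 ± 10.5 against 4.81 ± 0.75. Formative genes were higher in 9 of 13 cases (median 2.39, adjusted p = 0.00177, estimated-correlation adjusted p = 0.183), Rhox genes in 6 of 7 (median 2.98, adjusted p = 0.000583, estimated-correlation adjusted p = 0.109) and two-cell-like genes in 8 of 14 (median 1.1, adjusted p = 7.27e-05, estimated-correlation adjusted p = 0.0411). Neuroectoderm genes were higher in 5 of 10 with 1 lower (median 1.08, adjusted p = 0.0236, estimated-correlation adjusted p = 0.125). Other genes far higher than in DNMT WT were Dppa5a (1039 ± 32 against 19 ± 2.86), Lefty2 (112 ± 3.77 against 1.79 ± 0.125), Dnmt3l (72.6 ± 1.76 against 1.17 ± 0.0922), Rbmxl2 (41.7 ± 2.61 against 0.386 ± 0.192), Mymx (23.9 ± 1.54 against 0.13 ± 0.0998) and Tuba3a (34 ± 3.12 in DNMT KO, under 0.1 in DNMT WT). In DNMT KO at ESC D0, Dppa5a, Rbmxl2 and Tuba3a stood at 1049, 56.8 and 108 RPKM, so they did not rise from ESC D0 to EB D8. Dnmt3l was lower at ESC D0 than at EB D8, and Lefty2 and Mymx are not compared here.

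All 17 cardiac genes were lower in DNMT KO at EB D8 (median -2.88, adjusted p = 2.71e-08, estimated-correlation adjusted p = 0.125). Among these were the sarcomere genes Actc1 (1.49 ± 0.423 against 37.7 ± 10.2 RPKM), Tnnc1 (2.31 ± 0.358 against 31.1 ± 2.73) and Myl7 (6.62 ± 1.63 against 75.3 ± 21.1). Erythroid genes were lower in 15 of 17 cases with 1 higher (median -2.73, adjusted p = 5.6e-07, estimated-correlation adjusted p = 0.0921). Hbb-bh1 stood at 59.8 ± 3.92 against 3060 ± 24.2, log2 change -5.67, Hba-x at 31.5 ± 2.56 against 962 ± 9.65 and Hba-a1 at 3.83 ± 1.54 against 154 ± 11. Blood lineage genes were lower in 9 of 16 cases with 1 higher (median -1.5, adjusted p = 0.000201, estimated-correlation adjusted p = 0.0921). Gata1 stood at 1.11 ± 0.069 against 10.3 ± 0.0909, log2 change -2.75. Haematoendothelial genes were lower in 7 of 21 cases with 1 higher (median -0.51, adjusted p = 0.0176, estimated-correlation adjusted p = 0.374). Tal1 stood at 6.36 ± 0.732 against 17.5 ± 0.612, log2 change -1.39 and Runx1 at 0.721 ± 0.107 against 2.55 ± 0.158, log2 change -1.32, and Kdr missed the size threshold (12.7 ± 0.434 against 23.7 ± 0.498, log2 change -0.87, adjusted p = 2.34e-07). Endoderm genes were lower in 13 of 17 cases with 2 higher (median -1.66, adjusted p = 1.76e-05, estimated-correlation adjusted p = 0.0411). Rbp4 stood at 11.2 ± 1.37 against 253 ± 18.7. Imprinted genes were lower in 10 of 25 cases with 1 higher (median -0.80, adjusted p = 4.64e-05, estimated-correlation adjusted p = 0.0316). Among these were the growth factor gene Igf2 (1.87 ± 0.175 against 148 ± 19.7) and Dlk1 (3.0 ± 0.293 against 51 ± 5.34). Mesenchyme genes were lower in 9 of 14 cases (median -2.42, adjusted p = 0.000102, estimated-correlation adjusted p = 0.155). The collagen gene Col3a1 stood at 0.882 ± 0.132 against 48.3 ± 2.44. Hox genes were lower in 17 of 32 cases with 1 higher (median -1.06, adjusted p = 0.000164, estimated-correlation adjusted p = 0.0411). The extracellular matrix genes Nepn and Lum, at 70.4 ± 1.01 and 12.5 ± 0.978 RPKM in DNMT WT, were under 0.1 RPKM in DNMT KO, and Pyy stood at 1.04 ± 0.648 against 31.4 ± 2.69. No list-level call was made for Nodal pathway genes (5 higher and 2 lower of 10, adjusted p = 0.187), trophoblast genes (5 and 2 of 10, adjusted p = 0.295), interferon genes (1 and 4 of 13, adjusted p = 0.618), streak genes (2 and 2 of 15, adjusted p = 0.762), Wnt target genes (2 and 2 of 11, adjusted p = 0.862) or p53 target genes (1 and 1 of 15, adjusted p = 0.173). The same held for other methylation machinery (2 higher of 13, adjusted p = 0.324), housekeeping genes (1 higher of 10, adjusted p = 0.415), mitochondrially encoded genes (0 of 9, adjusted p = 0.971) and the 6 Tet and Dnmt genes (1 higher and 3 lower, adjusted p = 0.235).

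**Figure D4:**
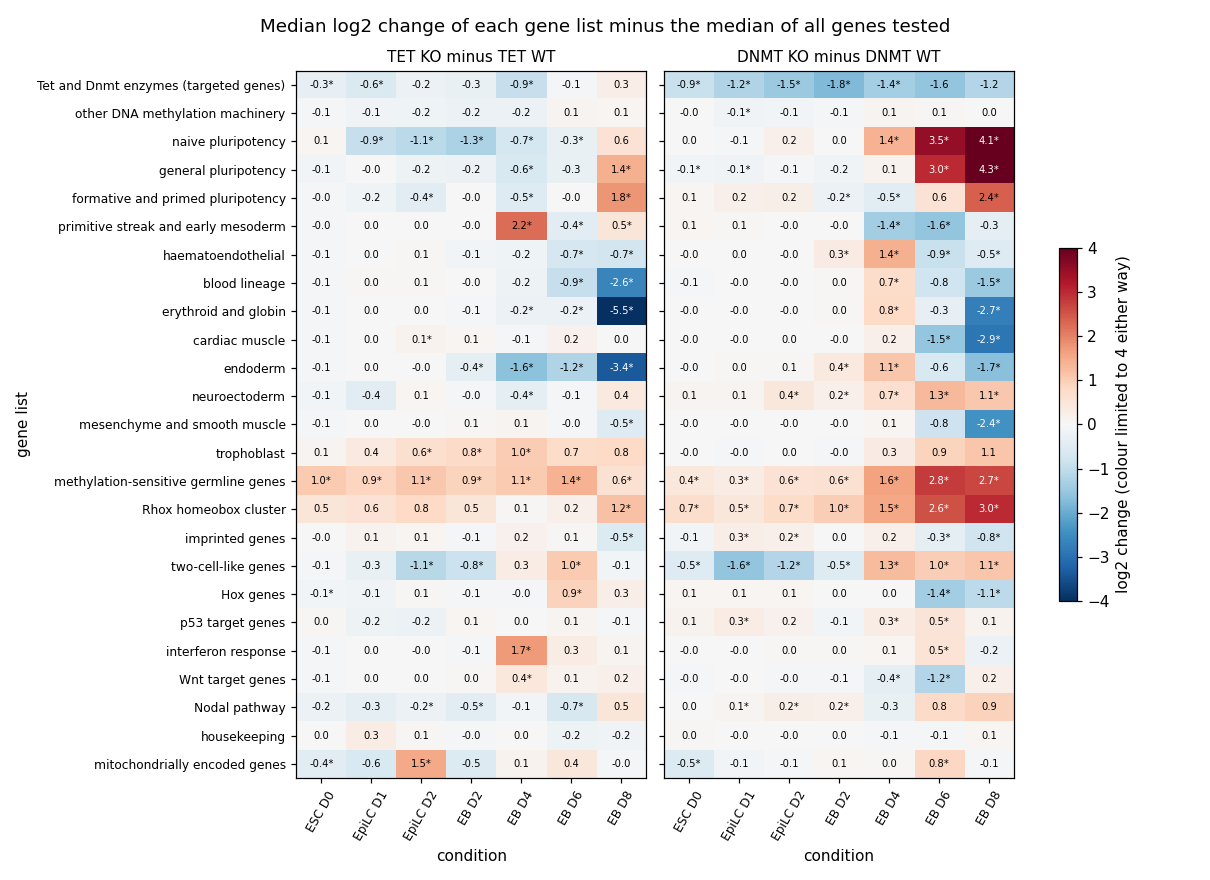
Median log2 change of each gene list (rows), minus the median of all genes tested, in TET KO and DNMT KO against the parental lines at the 7 conditions (columns), with colour for direction and size. Erythroid genes reached their lowest value in TET KO at EB D8, and naive pluripotency genes their highest in DNMT KO at EB D8.

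Whether the knockouts differed from each other was tested as the DNMT KO effect minus the TET KO effect, which calls 3154 genes at EB D8 (1368 higher and 1786 lower; 43.4% higher, 58.7% after centring). Cardiac genes had the lower difference in 15 of 17 cases with 1 higher (median -2.4, adjusted p = 3.65e-06, estimated-correlation adjusted p = 0.175) and Hox genes in 22 of 32 (median -1.51, adjusted p = 1.3e-05, estimated-correlation adjusted p = 0.0358). Naive genes had the higher difference in 15 of 16 cases (median 3.28, adjusted p = 3.94e-10, estimated-correlation adjusted p = 0.0887) and germline genes in 17 of 22 with 1 lower (median 1.85, adjusted p = 3.65e-06, estimated-correlation adjusted p = 0.0358). Erythroid genes, lower in both knockouts, fell less in DNMT KO for 14 of 17 genes (median 2.2, adjusted p = 8.08e-08, estimated-correlation adjusted p = 0.0826). Blood lineage genes did so for 10 of 16, with 1 the other way (median 1.58, adjusted p = 0.00015, estimated-correlation adjusted p = 0.0887). The knockouts, with separate controls, shared 304 higher genes at EB D8, where independent lists of these sizes would share 87.1, and 326 lower genes where they would share 57.5 (Fisher's exact test, adjusted p = 1.68e-94 and 1.84e-176 over 21 overlaps, taking genes as independent). Of genes higher in TET KO, 79 were lower in DNMT KO (81.2 for independent lists), and changes correlated across genes with r = 0.366. At EB D4 the overlaps went both ways: 89 genes were higher in both knockouts (52.4 for independent lists, adjusted p = 1.95e-06), 16 lower in both (3.7, adjusted p = 2.71e-06) and 63 higher in TET KO but lower in DNMT KO (15.2, adjusted p = 8.36e-23), and r was -0.131. Genes lower in TET KO but higher in DNMT KO were not counted at EB D4 or EB D8.

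The change from ESC D0 to EB D8 was also compared between knockout and parental line. It differed for 2022 genes in the TET lines and 3130 in the DNMT lines. In the TET lines the response was lower in TET KO for 16 of 17 erythroid genes (median -5.43, adjusted p = 5.94e-20, estimated-correlation adjusted p = 0.000793), 12 of 16 blood lineage genes (median -2.82, adjusted p = 7.26e-12, estimated-correlation adjusted p = 0.000793) and 13 of 17 endoderm genes (median -2.94, adjusted p = 2.96e-11, estimated-correlation adjusted p = 0.000793). In the DNMT lines it was higher for 14 of 16 naive genes (median 3.93, adjusted p = 2.54e-11, estimated-correlation adjusted p = 0.0192) and 8 of 10 general pluripotency genes (median 4.33, adjusted p = 9.99e-11, estimated-correlation adjusted p = 0.0192), and lower for 16 of 17 cardiac genes (median -2.89, adjusted p = 1.48e-09, estimated-correlation adjusted p = 0.0192). Called at all 7 conditions were 20 genes higher in TET KO, including Ddx4, Mael, Mov10l1 and Tex19.1, and 14 lower, including Nr1h5. In DNMT KO, 10 were higher at all conditions, including Dazl and Asz1, and 5 lower, namely Dnmt1, Dnmt3a, Ddx3y, Uty and Eif2s3y. With the replicate number as a block, EB D2 had 3 calls, 0 of them higher, so none of these 10 and not all of these 5 were then called at all conditions.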

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

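All tests of explanations in this part were chosen after the results were seen. The results below stood out because the change in DNMT KO against its parental line differed from that in TET KO. This was by a test of the difference itself (DNMT KO effect minus TET KO effect, limma). Medians here are on the log2 scale without subtraction of the median of all genes.

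The difference was called for 1214 genes at ESC D0, 1359 at EpiLC D1, 1619 at EpiLC D2, 1508 at EB D2, 2459 at EB D4, 3129 at EB D6 and 3154 at EB D8. Lists were tested for the difference at ESC D0, EpiLC D2, EB D4, EB D6 and EB D8, but not at EpiLC D1 or EB D2. In 9 cases at the conditions tested, over 8 gene lists, each knockout passed the list test in a direction opposite to the other, the medians had opposite signs and the difference passed the list test, although some of these medians lay near 0. Passing here was at the preset correlation. Many of the tests in single knockouts did not pass with an estimated correlation, such as streak and endoderm genes at EB D4 in both knockouts. At EB D4 the streak and early mesoderm list stood at 2.43 in TET KO and -1.40 in DNMT KO (difference -4.50, adjusted p = 1.28e-13, estimated-correlation adjusted p = 0.0791). Naive pluripotency genes stood at -0.50 and 1.39 at EB D4 (difference 1.78, adjusted p = 2.98e-11, estimated-correlation adjusted p = 0.175). At EB D6 they stood at -0.24 and 3.54 (difference 4.13, adjusted p = 2.81e-08, estimated-correlation adjusted p = 0.0358). Hox genes at EB D6 stood at 0.99 and -1.35 (difference -2.29, adjusted p = 8.17e-11, estimated-correlation adjusted p = 0.00518). Endoderm genes at EB D4 stood at -1.44 and 1.12 (difference 2.83, adjusted p = 1.05e-07, estimated-correlation adjusted p = 0.134), and erythroid genes at -0.05 and 0.79 (difference 0.84, adjusted p = 1.55e-08, estimated-correlation adjusted p = 0.0506). Neuroectoderm genes at EB D4 stood at -0.20 and 0.69 (difference 1.41, adjusted p = 3.20e-04, estimated-correlation adjusted p = 0.209), and Wnt targets at 0.62 and -0.39 (difference -1.06, adjusted p = 0.00602, estimated-correlation adjusted p = 0.314). Nodal pathway genes at EpiLC D2 stood at -0.20 and 0.22 (difference 0.51, adjusted p = 4.13e-04, estimated-correlation adjusted p = 0.0506).

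Splits of the libraries were counted for the counts given here and in the results above that compare groups of at least 3. For the difference between the knockout effects, knockout and parental labels were exchanged within each line pair, and 2 of 100 splits gave as many genes as the real one at EpiLC D2 (1619, highest other 1677), EB D6 (3129, highest other 3543) and EB D8 (3154, highest other 4348), the real split included. In each case the highest other split was the one that exchanges the labels of 1 line pair entirely, which adds the effects up. Without it the highest were 1238, 2765 and 2866. The share of splits is under 0.05, but the other splits mix knockout and parental libraries, which widens the spread within groups. The full exchange gave more genes than the real labels. These counts therefore do not decide whether the effects differed beyond chance. For the TET response between ESC D0 and EB D8 this scheme gave 2 of 100 (2022 genes, highest other 3215, and 1840 without the full exchange). A scheme that exchanged the day labels was run first and gave 16 of 100 splits as large (highest other 8521, and 6268 without the full exchange). That scheme breaks up the change over days itself, a structure of the samples far larger than the response difference. The exchange of knockout and parental labels was chosen after this outcome was seen.

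With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split, counted as 1 of 10, gave 1035 genes for TET KO at ESC D0, 1011 at EpiLC D1, 1206 at EpiLC D2, 1446 at EB D4, 766 at EB D6 and 1524 at EB D8. For DNMT KO it gave 243 at EpiLC D2, 2738 at EB D6 and 2880 at EB D8, and for TET WT against ESC D0 4219 at EpiLC D2 and 4994 at EB D8. The highest other split gave 0 genes in each of these except TET WT at EB D8, where it gave 1.

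Genes of chromosomes 8 and 14 were lower as a block in TET KO at ESC D0, at -0.44 and -0.46 against the median of all genes. Per-million scaling moves all genes of a library alike and drops out of such a difference, so shifts of -0.44 and -0.46 argue against it as their source. Each chromosome was divided by gene order into 3 segments with equal numbers of genes. Of the 6 segments of these chromosomes at ESC D0, the highest median was -0.42 and the lowest -0.49, while the lowest segment median elsewhere was -0.21, on chromosome 6, which is what a difference in copy number along whole chromosomes would give (3 copies against 2 give 0.585). On chromosome 14 at ESC D0 TET WT stood 0.61 above DNMT WT and TET KO 0.12 above it, so the shift lay in the parental line and argues against TET loss acting on these genes. The excess of TET WT over DNMT WT was 0.41 at EB D4, 0.23 at EB D6 and 0.03 at EB D8. A copy number that stayed the same over the course would not give this decline. On chromosome 8 TET KO stood at -0.46 against DNMT WT and TET WT at -0.04, so loss of TET and a copy number change in the knockout line cannot be told apart there, since the line and the genotype coincide.

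Calls in TET KO at EB D4 were mostly higher. Without TET WT replicate 2, the library with most reads on Gm42418, 939 genes were still called higher, 80.9% of the count with it, and 69.4% of calls were higher instead of 80.2%, which argues against that library as the whole cause but not against a part in it. With libraries centred on their medians 51.6% of calls were higher, but centring evens the directions whatever the cause, so per-million scaling and a real excess cannot be told apart. Of the 1160 higher genes, 72.2% were also higher in TET WT at EB D6 than at EB D4, but both comparisons share the TET WT libraries at EB D4, so TET KO being ahead on the same course and a different course cannot be told apart.

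Blood genes were lower and pluripotency genes higher at EB D8, and cells that kept the ESC D0 profile in DNMT KO bodies would leave ES cell genes at one common share of their ESC level. Over 140 such genes the kept level had quartiles of 11.6%, 25.3% and 51.6%, a ratio of 4.44, which argues against such cells as the whole cause, while ES-like cells with a profile changed outside 2i/LIF were not tested and remain open. Over 80 genes of 5 lists DNMT KO lay about as near to wild type at EB D4, at an RMS distance of 1.97 log2 units (1.95 to 2.01 by library) against 0.480 between the parental lines, as at EB D2 (1.99), and over all genes 0.699 from EB D4 against 0.41, so a delay and another course cannot be told apart. TET KO lay nearest to EB D6, at 1.36 (1.34 to 1.39) against 1.05, a ratio of 1.30, but over all genes at 0.676 against 0.366, with EB D8 as near (0.703), so the same holds there, and loss of each enzyme family remains open as the biological explanation.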

How the results depend on the processing

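Of the alternatives in this part, voom on recovered reads, the fit without libraries rich in Gm42418 reads, and the fit without genes of chromosomes 8 and 14 were chosen after the data were seen. Over 357 counts under alternatives, 304 lay within 1.5 times the count reported and 53 did not. Of the changes of named genes, 3576 kept direction and side of the threshold, 15 lost the call and 3 gained it. Many named genes were chosen from these data as large called changes, which favours keeping a call. These numbers therefore say little about other genes. Another 18 changes of named genes, called in neither fit, changed sign, and 0 called changes turned in direction. For the blood lists, 104 values kept the call and 4 lost it. Where a value moved, the cause was not tested, except that a larger pseudocount shrinks changes of low genes by construction.

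Of 21 counts, voom moved 14 beyond 1.5 times, and the pseudocount settings 12, 11 and 12. With 0.1 RPKM, TET KO calls numbered 1935 at ESC D0, 1904 at EpiLC D1, 2221 at EpiLC D2, 1918 at EB D2, 2362 at EB D4, 1443 at EB D6 and 2392 at EB D8. DNMT KO calls then numbered 381, 259, 534, 305 and 1480 from ESC D0 to EB D4. With 1 RPKM, TET KO had 637, 647, 753, 666, 947 and 449 from ESC D0 to EB D6, and DNMT KO 94, 82, 134, 87 and 557 from ESC D0 to EB D4. With the deposited log2 values and none, TET KO had 2198, 2235, 2436, 2025, 2568, 1652 and 2611 over the 7 conditions, and DNMT KO 408, 251, 524, 308 and 1490 up to EB D4. Runx1 in TET KO at EB D8 lost its call with 1 RPKM (log2 change -0.87).

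Voom on the recovered reads (98.0% of values between 1 and 100 reads were whole numbers) tested 15264 genes and called 2317, 2305, 2534, 2032, 2562, 1771 and 2662 in TET KO, 478, 304, 590, 357, 1774 and 4137 in DNMT KO from ESC D0 to EB D6, and 3818 in DNMT WT at EpiLC D2 against ESC D0. With only the libraries of the groups compared, DNMT KO had 68 calls at EpiLC D1 and 61 at EB D2. The filter, both other scalings, all 79 libraries in 1 fit, and the fits without genes of chromosomes 8 and 14 or libraries rich in Gm42418 reads moved no count by more than 1.39 times. Etv2 in DNMT KO at EB D2 also lost its call with no filter, with only the libraries of the groups compared, and without DNMT WT replicate 1 or 2 or DNMT KO replicate 2 (lowest log2 change 0.80). H19 there missed the size threshold after quantile normalization (0.98). Leaving out 1 library moved 1 count beyond 1.5 times: DNMT KO at EB D2 spanned 135 to 372, the highest without DNMT KO replicate 3. Tet1 in TET KO at EB D4 missed the size threshold without TET WT replicate 1 (-0.96).

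The replicate number is shared across groups, and only 14 of 35 libraries with a partner correlated best with the partner of their own number, so it was no block in the fits reported. With it as a block, DNMT KO at EB D2, which shares 2 numbers, had 3 calls instead of 174, and Dnmt1 and Dnmt3b were no longer called there (adjusted p = 0.129 and 0.161), nor were Sox18, Grb10, H19 and Etv2, nor Tet1 in TET KO at EB D2 (adjusted p = 0.0645). No paired analysis was possible for DNMT KO at EpiLC D1 because 1 DNMT WT library there could be tied to no number, which left 1 number in both groups.

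Of the 3 blood lists at EB D8, with an estimated correlation 4 calls were lost. Medians here are without subtraction of the median of all genes: haematoendothelial genes in TET KO (-0.63, adjusted p = 0.14) and DNMT KO (-0.50, adjusted p = 0.374), and in DNMT KO blood lineage (-1.49, adjusted p = 0.0921) and erythroid genes (-2.72, adjusted p = 0.0921). Depth limits low genes: 1 read on a 2 kb gene was worth 0.0644 RPKM in the shallowest library.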

Other observations

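The tests of wild-type stage in this part were chosen after the results were seen. Trophoblast genes were higher in TET KO at EB D4 in 6 of 10 cases (median 1.01, adjusted p = 0.0229, estimated-correlation adjusted p = 0.188), with Cdx2, a regulator of trophectoderm and posterior body, at 11.3 ± 1.44 against 0.266 ± 0.128 RPKM and Tfap2c at 7.5 ± 0.833 against 1.42 ± 0.603 (n = 3 and 3). Formative and primed genes were lower in 4 of 13 cases (median -0.52, adjusted p = 8.04e-05, estimated-correlation adjusted p = 0.423), with Foxd3 at 1.52 ± 0.155 against 14.8 ± 3.28. Nodal pathway genes at EB D4 went both ways, with 3 higher and 2 lower of 10 (adjusted p = 0.472): the antagonist gene Cer1 (14.9 ± 1.4 against 0.172 ± 0.145) rose and Gdf3 (2.38 ± 0.424 against 19.6 ± 3.84) fell. At EB D2 the same pathway was lower in 3 of 10 cases (median -0.46, adjusted p = 0.00604, estimated-correlation adjusted p = 0.15), with Lefty2 at 19.2 ± 0.361 against 91.2 ± 6.64 (n = 2 and 3). Etv2, a factor that starts blood and vessel fate, was lower in TET KO at EB D4 (0.894 ± 0.109 against 8.32 ± 2.74), although the haematoendothelial list as a whole was not called (2 higher and 4 lower of 21, adjusted p = 0.0834).

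In DNMT KO at EB D2, Sox18 (17.3 ± 1.29 against 4.09 ± 0.649 RPKM, n = 2 and 3) was already higher. Etv2 (11.5 ± 3.07 against 5.19 ± 0.931) was called too, but 6 alternatives ended its call, such as leaving out DNMT KO replicate 2 (log2 change 0.80). Also higher were the imprinted genes Grb10 (9.23 ± 1.64 against 2.59 ± 0.198) and H19 (91.5 ± 5.16 against 43.5 ± 1.16, not called after quantile normalization, log2 change 0.98), with 4 of 25 imprinted genes higher (adjusted p = 0.187). With the replicate number as a block, none of Sox18, Etv2, Grb10 and H19 was called (adjusted p = 0.205, 0.246, 0.205 and 0.21). At EpiLC D1 the imprinted RNAs Rian (4.57 ± 0.156 against 0.799 ± 0.087) and Meg3 (2.02 ± 0.127 against 0.449 ± 0.0336) were higher (median 0.28, adjusted p = 0.00586, estimated-correlation adjusted p = 0.114; n = 3 and 2). Among genes of the wild-type course, imprinted genes were higher in DNMT WT at EB D8 than at ESC D0 in 21 of 25 cases with 2 lower (median 3.25, adjusted p = 2.35e-07, estimated-correlation adjusted p = 0.00219), and germline genes were lower in 18 of 22 (median -2.35, adjusted p = 5.41e-07, estimated-correlation adjusted p = 0.00254).

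Chromosome 1 was lower in embryoid bodies than in ESCs of DNMT WT, with medians of -0.51 at EB D2 and -0.45 at EB D8 over 546 genes, against 0.04 and -0.06 in TET WT. EpiLCs of DNMT WT stood at -0.06 and -0.03. These medians are minus the median of all genes. Against DNMT WT at the same condition, TET WT stood at -0.49 at ESC D0, -0.40 at EpiLC D1 and -0.41 at EpiLC D2. At EB D2 and EB D8 it stood at 0.01 and -0.08. TET KO stood at -0.46, -0.43 and -0.44 against DNMT WT at ESC D0, EpiLC D1 and EpiLC D2, and at -0.01 at EB D2. The excess thus lay in the ESC and EpiLC libraries of DNMT WT, and these values do not show that it was lost through differentiation. DNMT KO differed from DNMT WT on chromosome 1 by 0.02 at ESC D0 and -0.04 at EB D2, so it shared the difference between ESC D0 and EB D2. The 3 segments of chromosome 1 in DNMT WT at EB D2 stood at -0.50, -0.55 and -0.47 against ESC D0. Comparisons of embryoid bodies with ESC D0 in the DNMT lines include this shift. Ddx3y was higher in TET KO than in TET WT at ESC D0 (24.8 ± 1.48 against 11.6 ± 0.556 RPKM, n = 3 and 3), while Y-linked Eif2s3y was lower (4.12 ± 0.432 against 10.2 ± 0.374).

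A hypothesis from these data is that TET KO bodies at EB D8 may sit near an earlier wild-type stage for blood and pluripotency genes. Over 80 genes of 5 lists their RMS distance to TET WT was 1.36 at EB D6, 1.61 at EB D4 and 3.08 at EB D8. With all genes the nearest stage, again EB D6, lay 1.85 times as far as the parental lines lay from each other. EB D8 was then about as near (0.703 against 0.676), so the hypothesis does not extend to all genes. The distance over all genes does not test it for the 5 lists. The genes were chosen from the lists that moved, and a time course with more days would be needed to tell a delay from another course.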
